A study of Mus musculus with 4 samples.

How the data were processed

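RNA polymerase II (Pol II) was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) with an antibody against the N-terminus of Rpb1, in V6.5 mouse embryonic stem cells, per the labels. The 4 libraries came from cells with a short hairpin RNA against Spt4 (shSpt4), Spt5 (shSpt5) or NelfE (shNelfE) or with a control hairpin (shControl), 1 library per group. Hairpins acted for about 4 days and flavopiridol was given at 1 µM for 1 h before fixation, per the labels' protocols. Chromatin was sheared by sonication, and the recovered DNA was amplified by linker-mediated PCR and selected for size on a gel, per the labels' protocols. The knockdown libraries shared a flow cell and came from cells grown for 2 passages without feeder cells, and the control library came from another flow cell and from cells grown for 1 passage without feeders, per the labels. The background library of whole cell extract named in the series' design was not used here.

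The deposited values were aligned read positions, 1 signed number per read with the sign giving the strand, per the file headers. Reads were aligned with Bowtie to the mouse build mm8, with options that allowed 2 mismatches in the first 36 bases (-n 2, -l 36), a summed mismatch quality of 70 (-e 70) and at most 2 reported hits (-k 2, -m 2), per the file headers and the submitters' processing notes. The aligner version is not given in the sources used here. Each file split its reads into 2 categories. The headers do not state what separates them, and the line count of the second category was even in all 4 libraries. The first category was used, and the second was read only for its share. No header or label states whether duplicates were removed before deposit, and repeated positions were present in all 4 files. The values carried no normalization, per the file headers.

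From these positions, 1 tag per position and strand was kept. That left 2646944 tags in shSpt4, 3116313 in shSpt5, 2938052 in shNelfE and 3170090 in shControl. Strand cross-correlation on chromosomes 11 and 19 of the libraries together gave an offset of 82 bp, and every tag was moved by 41 bp toward the fragment centre. Enriched regions were called on the 4 libraries thinned to the depth of the shallowest and pooled, so that each library weighed the same. Windows of 250 bp on a grid of 50 bp were kept at a Poisson p of 1e-9 against the larger of the genome-wide density and the density within 5000 bp on each side, leaving out the nearest 1000 bp. Windows within 500 bp of each other were merged, and the summit was the highest point of the pooled tags. All coordinates are 1-based positions on mm8. The gene table at hand describes another assembly, so no region was given a gene name and no promoter or gene body was defined.

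Tags in each region were scaled to 1000000 kept tags per library (normalised tags). A ratio between libraries has an exact 95% interval, from the binomial distribution of a region's tags given their sum. A region was called higher or lower when its ratio was at least 2 or at most 0.5 and the interval excluded 1. Log2 ratios used a pseudocount of 0.5 tags, and the interval of a median over regions came from order statistics, with regions as the units. The focal ratio, a stand-in for the travelling ratio of promoter over gene body that needs no annotation, divided the tag density within 500 bp of the summit by the density 1 to 3 kb away on both sides. Aggregate profiles averaged normalised tags per kb around the summits, with intervals from 500 bootstrap draws of regions. Intervals for shares of tags were exact binomial. All intervals cover counting error or the spread over regions or chromosomes of these libraries. PCR copies are not independent molecules, and a ratio compares 2 libraries, not 2 conditions. No p-value was computed across regions, which are not replicates.

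Calls were set beside 100 simulations in which the libraries differed in depth alone (20 simulations for the calls scaled by the median ratio). Groups of regions were set beside 10000 random lists of the same size matched on mean tags, in 20 classes, and the percentile of the group's median among them is a description of these libraries. Correlations between comparisons that share the control library were set beside simulated ones. The named regions were the 10 with most normalised tags averaged over the libraries, the 10 highest and 10 lowest against the control in each knockdown among regions with at least 50 tags in the pair of libraries that passed the call, and the 3 highest and 3 lowest for the knockdowns among each other. Where fewer passed, those that passed were named.

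The tests, the named-region rule and the following alternatives were set before the data were examined: keeping all tags, a Poisson p of 1e-12, regions from the control library alone, scaling by tags outside regions or by the median ratio, thinning to equal depth, subtracting background, a narrower centre and flank, unmoved tags, a ratio of 1.5, and regions with at least 50 tags. Regions from the knockdown libraries, isolated regions, autosomes and X only, scaling by windows of 1 Mb with no region, a wider profile centre, profile background subtraction and held-out summits were added after the data had been seen. The calculations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

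The calls were tested on simulated data with 200 changed regions per fold among 14103. The changed regions were drawn only from those above a minimum mean level of normalised tags, so recovery at weaker regions was not measured. For shSpt5 against shControl, 100% of regions at a fold of 4 and 99% at a fold of 3 were recovered, as were 93% at a fold of 0.25 and 85% at a fold of 0.333. In shSpt4 against shControl the recovery was 100%, 98.5%, 95% and 86%, and in shNelfE against shControl it was 99.5%, 98.5%, 94.5% and 86.5%. Of 300 simulated peaks, those with a mean of 40 pooled tags were found in 100%, those with 20 in 89.3% and those with 10 in 15.7%, so that weakly occupied sites are underrepresented.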

Results

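Pol II occupancy was profiled across the genome of V6.5 mouse embryonic stem cells carrying hairpins against factors that act on paused Pol II. Spt4 and Spt5 form DSIF and NelfE is a subunit of NELF. Both complexes bind Pol II soon after it starts transcription and take part in holding it near promoters. All 4 cultures received flavopiridol, which inhibits Cdk9, the kinase that releases paused Pol II into gene bodies. The comparisons thus ask how Pol II that is kept from productive elongation depends on each factor. The antibody recognises Rpb1, the largest Pol II subunit, whatever its phosphorylation.

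Each group held 1 library, so no difference has a replicate check. The deposited reads of the first category numbered 2881229 in shSpt4, 3788237 in shSpt5, 3272816 in shNelfE and 3486288 in shControl. Repeated positions made up 8.13%, 17.7%, 10.2% and 9.07% of them and were reduced to 1 tag each. The control library came from another flow cell than the knockdown libraries, so flow cell and knockdown cannot be told apart in any comparison with it. RNA and protein of the targeted genes were not measured in these libraries, and knockdown was not checked here.

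Pol II tags formed 14103 enriched regions, 5 of them mitochondrial, with a median width of 650 bp. The middle 90% of widths ran from 250 to 1550 bp. No background library was used, so a region marks enriched tags and was not shown to be bound by Pol II. Together the regions covered 10.9 Mb, or 0.435% of the occupied genome, and they held a median of 25 tags in shControl. Chromosome 11 carried 1165 of them, the most of any chromosome. The control library had 20.3% of its tags in regions (95% interval 20.3 to 20.4%). In shSpt4 the share was 16.9% (16.8 to 16.9%), in shNelfE 15.4% (15.4 to 15.5%) and in shSpt5 12.3% (12.2 to 12.3%). All knockdown libraries thus had a smaller share of their tags in the regions, with shSpt5 lowest. Weaker enrichment and less Pol II at the regions would both lower this share.

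The 10 regions with most tags ran from below to above the typical level. Chromosome 17, 39451101 to 39454750, ranked first with 3572 tags in shControl, and its ratio to the control was 0.799 in shSpt4 (0.758 to 0.842), 0.595 in shSpt5 (0.563 to 0.628) and 0.866 in shNelfE (0.824 to 0.910). It spanned 3650 bp, and with 1 tag kept per position and strand the counts of so dense a region have a ceiling. That ceiling draws its ratios toward 1, which the intervals leave out. Chromosome 1, 88357101 to 88360200, was lower still, at 0.721 (0.635 to 0.818), 0.494 (0.431 to 0.565) and 0.797 (0.708 to 0.898). Scaled by total tags, chromosome 13, 23562201 to 23563700, was near the control's level, at 1.02 (0.900 to 1.15) in shSpt4, 1.03 (0.913 to 1.16) in shSpt5 and 0.964 (0.853 to 1.09) in shNelfE. Regions on chromosome 10 (39946851 to 39948550), chromosome 5 (115750101 to 115751850), chromosome 1 (72187751 to 72189300) and chromosome 6 (124706101 to 124707350) had ratios from 1.01 to 1.41 in every knockdown library, above the median region of each. All 5 of these regions depend on the scaling, because windows of 1 Mb without any region had ratios of 1.32 in shSpt4, 1.54 in shSpt5 and 1.27 in shNelfE. Measured against those windows, the chromosome 13 region was lower than the control in all 3 knockdown libraries, and the other 4 were lower in shSpt5. The regions on chromosomes 5 and 6 stayed above it in shSpt4 and those on chromosomes 5 and 1 in shNelfE, and the other 2 in each library turned lower.

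The shSpt4 library had modestly fewer normalised tags at most regions. Normalised tag counts were below the control at 70.8% of regions, with a median ratio of 0.811 (log2 -0.30, 95% interval -0.31 to -0.29). In shSpt4, 1316 regions were called lower and 169 higher, where libraries that differed in depth alone gave means of 119 and 122. The lowest ratios were at chromosome 10, 75375801 to 75376350, with 7 tags against 78 in shControl (ratio 0.107, 0.0418 to 0.232), at chromosome 18, 36406401 to 36407700, with 8 against 73 (0.131, 0.0546 to 0.273), and at chromosome 12, 103105651 to 103106650, with 8 against 69 (0.139, 0.0577 to 0.289). Of the 10 lowest regions, 9 were also called lower in shSpt5, where their median ratio was 0.203, and 3 in shNelfE, where it was 0.547. Choosing regions by a low ratio favours high counts in the control, which by itself lowers the other ratios to that library, so these overlaps have no value for unchanged libraries beside them.

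Some regions ran against this reduction in shSpt4. Its 169 higher calls stood beside 122 by depth alone, so counting error may account for a large part of them. The intervals of the regions named here are not adjusted for choosing the extremes. The highest ratio was at chromosome 2, 13491551 to 13492950, with 48 tags against 14 (ratio 4.11, 2.23 to 8.06). Chromosome 14, 71971851 to 71973400, had 108 against 39 tags (3.32, 2.28 to 4.91), and chromosome 17, 28821051 to 28822350, had 165 against 76 (2.60, 1.97 to 3.46). Of the 10 highest regions, 2 were also called higher in shSpt5 and 1 in shNelfE, overlaps that the choice on the shared control favours. Relative to the median region the calls were 546 lower and 389 higher, and relative to windows with no region they were 3258 lower and 42 higher. Under the latter scaling 7 of the 10 highest regions kept their call, and the chromosome 17 region did not.

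The shSpt5 library had the fewest normalised tags at the regions among the 3 knockdown libraries. Normalised tag counts were below the control at 84.7% of regions, and the median ratio was 0.585 (log2 -0.77, -0.79 to -0.76). In shSpt5, 4043 regions were called lower and 111 higher, against 120 and 115 by depth alone. The loss was near complete at single regions: chromosome 13, 44913351 to 44914450, had 5 tags against 335 in shControl (ratio 0.0152, 0.00490 to 0.0358), while shNelfE held 149 and shSpt4 held 76. Chromosome 7, 143315501 to 143316200, had 2 tags against 54 (0.0377, 0.00445 to 0.143), and chromosome 3, 41709951 to 41711500, had 4 against 106 (0.0384, 0.0103 to 0.101).

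**Figure D1:**
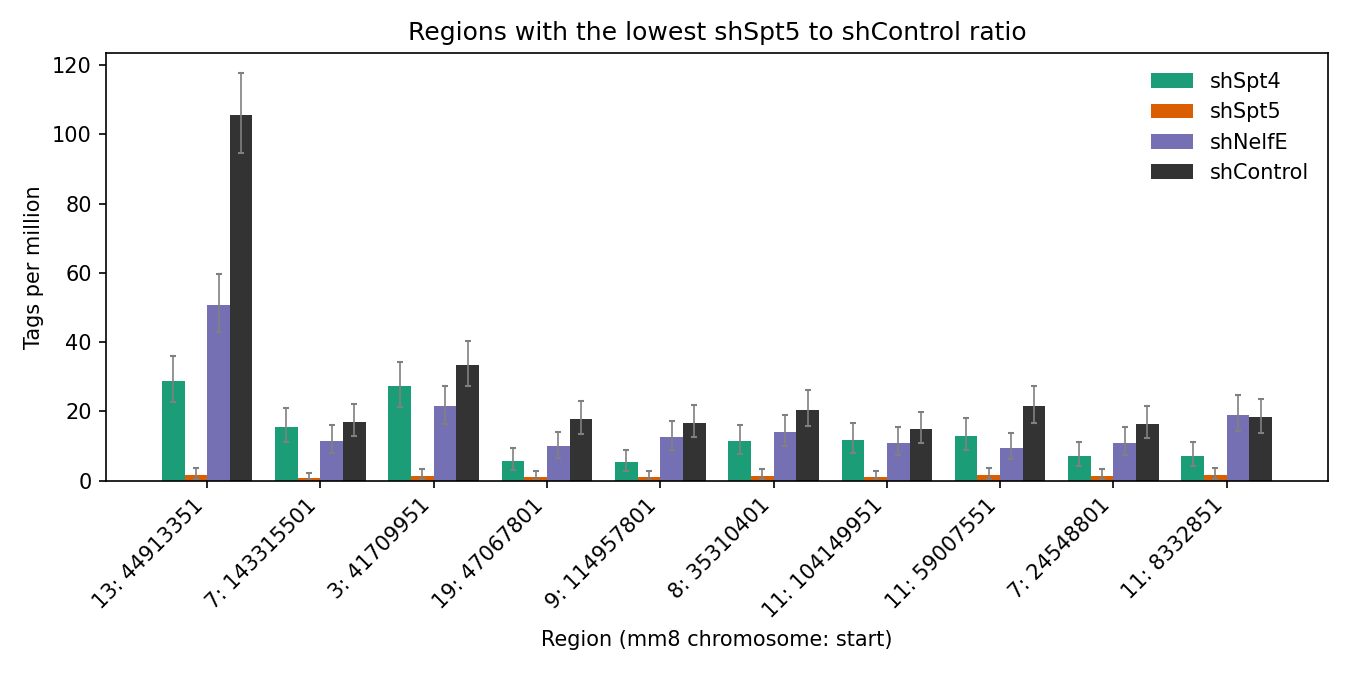
Normalised tags (vertical axis) in the 10 regions with the lowest ratio of shSpt5 to shControl, named by chromosome and mm8 start, 1 bar per library with exact 95% Poisson intervals as error bars. In shSpt5 these regions held 5 tags or fewer each. They were chosen on the ratio of shSpt5 to shControl, which by itself favours low shSpt5 and high shControl counts.

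The 10 regions lowest in shSpt5 had a median ratio of 0.0601 there, 0.495 in shSpt4 and 0.672 in shNelfE, and 5 and 2 of them were called lower in the latter libraries. They were chosen on their shSpt5 ratio, a choice that by itself puts the other libraries above shSpt5. It also favours high counts in the control, which lowers the other ratios to that library. At chromosome 3, 41709951 to 41711500, the ratio was 0.813 (0.595 to 1.11) in shSpt4 and 0.641 (0.462 to 0.884) in shNelfE. Among the 10 highest regions in shSpt5 were chromosome 6, 4697201 to 4697950, with 46 tags against 12 (3.90, 2.03 to 8.09), and 3 stretches of the mitochondrial genome, such as 1751 to 4400 with 696 against 291 (2.43, 2.12 to 2.80). The 111 higher calls of shSpt5 were no more than the 115 of depth alone, so counting error may account for many of them. These intervals are not adjusted for choosing the extremes. Relative to the median region, shSpt5 had 964 lower and 698 higher calls, where depth alone gave 130 and 114. Relative to windows with no region it had 8676 lower and 16 higher calls, and of the 10 highest regions only the one on chromosome 6 kept its call.

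The shNelfE library had fewer normalised tags than the control at more regions than shSpt4 did, with fewer strong losses. Normalised tag counts were below the control at 78.0% of regions, and the median ratio was 0.759 (log2 -0.40, -0.41 to -0.39). In shNelfE, 981 regions were called lower and 81 higher, against 119 and 120 by depth alone. The lowest ratio was 0.211 (0.0908 to 0.437) at chromosome 18, 70693201 to 70694000, with 9 tags against 46, and the next was 0.237 (0.111 to 0.462) at chromosome 8, 125927401 to 125927800, with 11 against 50. Of the 10 lowest regions, 7 were also called lower in shSpt5 and 3 in shSpt4, overlaps that the choice on the shared control favours.

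Only 5 regions with at least 50 tags were called higher in shNelfE. Over all regions its 81 higher calls were fewer than the 120 that depth alone gave, so counting error may account for many of them. The intervals of the regions named here are not adjusted for choosing the extremes. Chromosome 4, 116687451 to 116688750, was higher in all 3 knockdown libraries, with 293 tags in shNelfE against 154 (2.05, 1.68 to 2.51) and ratios of 2.08 (1.70 to 2.56) in shSpt4 and 2.12 (1.74 to 2.59) in shSpt5. These 3 ratios share 1 control count. Normalised tags were 101 in shSpt4, 103 in shSpt5 and 99.7 in shNelfE, against 48.6 in shControl. A low count in that 1 library would raise all 3 ratios, so their agreement is not a separate check. Chromosome 6, 47717251 to 47718300, had 44 tags against 19 (2.50, 1.43 to 4.53), with 1.20 (0.600 to 2.39) in shSpt4 and 1.18 (0.608 to 2.30) in shSpt5. Relative to the median region shNelfE had 246 lower and 261 higher calls, and relative to windows with no region it had 3077 and 25. Under the latter scaling neither of the regions on chromosomes 4 and 6 kept its call, and of the 5 only chromosome 5, 115359351 to 115360300, did, with 36 tags against 15 (2.59, 1.38 to 5.09, by total tags).

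**Figure D2:**
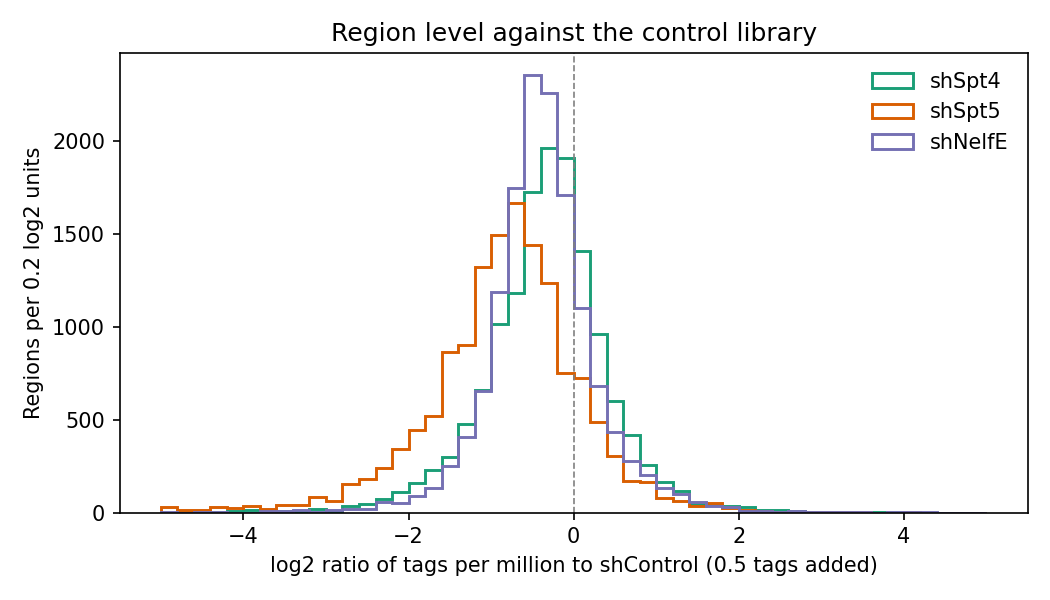
Distribution of the log2 ratio of normalised tags to shControl over the 14103 regions (horizontal axis, values beyond 5 in either direction drawn at the edge) as the number of regions per bin of 0.2 (vertical axis), 1 line per knockdown library. The medians lie at -0.30 in shSpt4, -0.77 in shSpt5 and -0.40 in shNelfE.

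The spread of regional change also differed between the knockdown libraries. The standard deviation of the log2 ratios to the control was 0.93 in shSpt5, 0.77 in shSpt4 and 0.66 in shNelfE, where libraries that differed in depth alone gave 0.60, 0.63 and 0.61. Those simulated values assume unchanged levels, and the lower tag counts of shSpt5 raise its counting error, so the order of the spreads is not free of it.

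Relative to the control, normalised tags were lower near the summits of the regions than in their flanks. Within 150 bp of the summit the density was 28.0 normalised tags per kb in shControl, 23.0 in shSpt4, 20.9 in shNelfE and 16.0 in shSpt5. The ratio to the control in shSpt5 was 0.571 (0.565 to 0.578) within 150 bp and 0.780 (0.769 to 0.791) at 1 to 2 kb. In shNelfE these ratios were 0.746 (0.741 to 0.752) and 0.868 (0.859 to 0.877), and in shSpt4 they were 0.822 (0.814 to 0.829) and 0.896 (0.885 to 0.905). At the 7408 isolated regions, with no other summit within 20 kb, the shSpt4 ratio at 1 to 2 kb was 1.00 (0.983 to 1.02). With local background taken off it was 1.03 (0.996 to 1.08), so that by total tags its flanks were not lower there. Relative to windows of 1 Mb with no region, which stood at 1.32 in shSpt4, these flanks were lower. Over all regions, the central ratio divided by the ratio at 1 to 2 kb was 0.732 (0.720 to 0.745) in shSpt5, 0.860 (0.851 to 0.871) in shNelfE and 0.917 (0.906 to 0.929) in shSpt4. At isolated regions with local background taken off it was 0.686, 0.836 and 0.803, so that the order of shNelfE and shSpt4 turned.

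**Figure D3:**
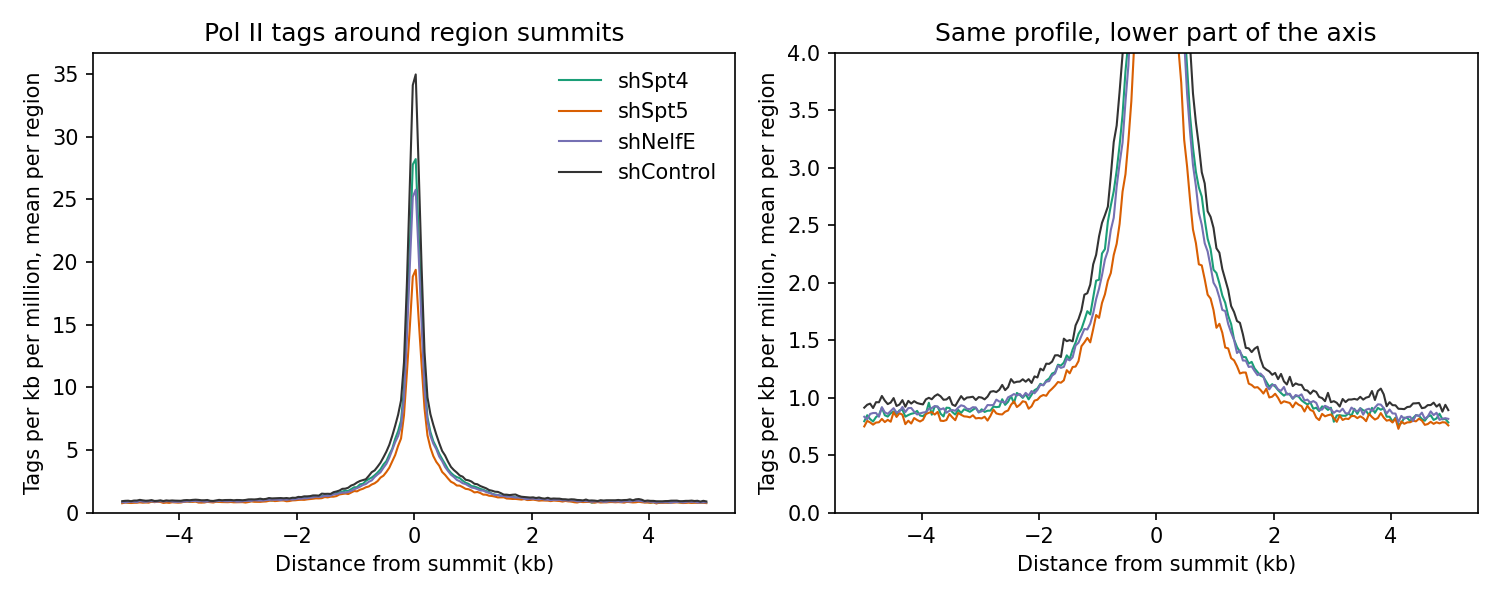
Mean normalised Pol II tags per kb (vertical axis) by distance from the summit in kb (horizontal axis), 1 line per library, over the whole range on the left and over its lower part on the right. The control library peaks highest and shSpt5 lowest, with 28.0 and 16.0 within 150 bp of the summit.

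**Figure D4:**
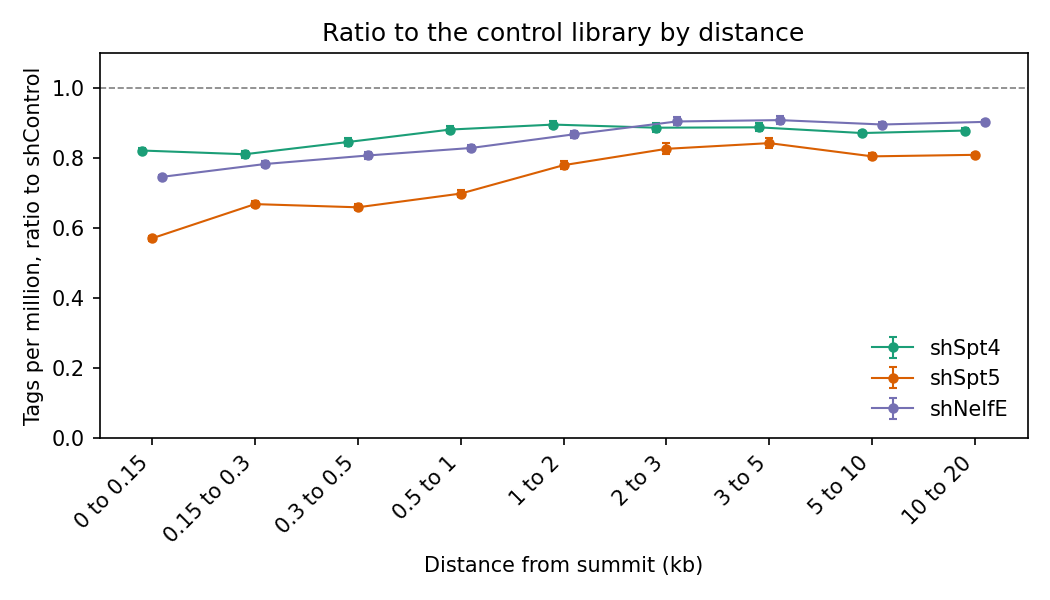
Ratio of normalised tags in each knockdown library to shControl (vertical axis) by distance from the summit in kb (horizontal axis), with 95% bootstrap intervals over regions as error bars and a dashed line at 1. The shSpt5 ratio goes from 0.571 at the summit to 0.780 at 1 to 2 kb.

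Region by region, the centre was lower relative to the flanks as well. The median focal ratio, central over flanking density, was 10.5 in shControl, 8.56 in shSpt4, 8.36 in shNelfE and 6.52 in shSpt5. Against the control its median log2 difference was -0.68 in shSpt5 (-0.70 to -0.66), -0.33 in shNelfE (-0.34 to -0.30) and -0.28 in shSpt4 (-0.30 to -0.25). No background was taken off in these values, and more background by itself lowers a focal ratio. Windows of 1 Mb with no region had ratios of 1.32 in shSpt4, 1.54 in shSpt5 and 1.27 in shNelfE. The focal ratio alone thus cannot tell weaker enrichment from a changed shape. With background subtracted, the differences of shSpt5 and shNelfE were smaller and kept their direction. The regions with no other within 10 kb had lower focal ratios against the control than crowded ones, with -0.77 against -0.48 in shSpt5, -0.38 against -0.22 in shNelfE and -0.35 against -0.15 in shSpt4. The medians of the regions with no other within 10 kb lay below all 10000 matched random lists in each library. At crowded regions the flanks can hold a neighbouring region that is lower too. That by itself weakens the focal difference there, and matching on mean tags does not remove it. Wide regions had lower focal ratios against the control than narrow ones, with -0.79 in the 4940 widest and -0.55 in the 4618 narrowest in shSpt5, -0.37 and -0.24 in shNelfE, and -0.31 and -0.21 in shSpt4. The centre has the same width at all regions, so more background in it at narrow ones may add to this contrast.

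The level also varied with the occupancy of a region. In 4 classes of regions from fewest to most tags, the median log2 ratio was -0.27, -0.43, -0.36 and -0.23 in shSpt4, so that the middle classes were lowest. It was -0.76, -0.87, -0.79 and -0.74 in shSpt5, and -0.25, -0.39, -0.43 and -0.42 in shNelfE. Background makes up more of the tags in the class with fewest tags. Its ratio to the control in windows without regions was above that of the regions, which may raise the values of this class. That part was not tested. The 398 regions on chromosome X stood apart in shSpt4, with a median log2 ratio of -0.11 against -0.31 on autosomes, above all matched lists. In shSpt5 their median was -0.64 (percentile 99.8), and in shNelfE it was -0.41 (percentile 33.7). Tags on X between regions were higher too, with ratios in windows without regions of 1.41 in shSpt4, 1.64 in shSpt5 and 1.32 in shNelfE, against 1.32, 1.54 and 1.27 on autosomes.

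The knockdown libraries shared a flow cell, and the comparisons among them set the subunits of DSIF, and DSIF and NELF, side by side. Normalised tags were lower in shSpt5 than in shSpt4 at 75.2% of regions, with a median ratio of 0.729 (log2 -0.46, -0.48 to -0.44). In that comparison 1748 regions were called lower and 148 higher, or 635 and 522 relative to the median region. The lowest ratios of shSpt5 to shSpt4 were at chromosome 3, 41709951 to 41711500 (0.0472, 0.0125 to 0.126), at chromosome 13, 44913351 to 44914450 (0.0559, 0.0176 to 0.136), and at chromosome 9, 64973101 to 64974000, with 26 tags against 224 (0.0986, 0.0630 to 0.148). The focal ratio was lower in shSpt5 than in shSpt4 by a median log2 difference of -0.39 (-0.41 to -0.37). A shared flow cell does not make these libraries alike. The shSpt5 library had 12.3% of its tags in regions, against 16.9% in shSpt4 and 15.4% in shNelfE. Its repeated positions were 17.7%, against 8.13% and 10.2%. Weaker enrichment in shSpt5 would lower both its level and its focal ratio against either library. Scaling by windows with no region was not run among the knockdowns.

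The shNelfE and shSpt4 libraries were close in typical level and differed at particular regions. The median ratio of shNelfE to shSpt4 was 0.935 (log2 -0.10, -0.12 to -0.08), with 379 regions called higher and 415 lower, or 492 and 312 relative to the median region. Chromosome 18, 36406401 to 36407700, had 42 tags in shNelfE and 8 in shSpt4 (ratio 4.73, 2.19 to 11.7), and chromosome 17, 28821051 to 28822350, had 37 and 165 (0.202, 0.137 to 0.290). Their focal ratios differed by a median of -0.03 (-0.05 to -0.01), a direction that turned with background subtraction. Against shSpt5, shNelfE was higher at most regions, with a median ratio of 1.30 (log2 0.37, 0.37 to 0.39) and 1676 regions called higher and 182 lower, or 802 and 530 relative to the median region. The median log2 difference in focal ratio was 0.34 (0.32 to 0.36). Chromosome 11, 8332851 to 8334250, had 56 tags in shNelfE and 5 in shSpt5 (11.9, 4.80 to 38.0).

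Many regions were lower in more than 1 knockdown library. The lower calls of shSpt4 and shSpt5 had 913 regions in common, where independent lists would share 377 and unchanged libraries against the same control shared 11.9. For shSpt4 and shNelfE the number was 345 (91.5 and 11.4), and for shSpt5 and shNelfE it was 634 (281 and 12.3). Neither value is a full reference for the overlap. The unchanged libraries had no general drop in level and gave a mean of 119 lower calls in shSpt4, against 1316 observed. Independent lists leave out the shared control. Shared higher calls numbered 34, 16 and 13 for these pairs. The pairs with shNelfE lay below the 20.1 and 20.9 of unchanged libraries, and shSpt4 with shSpt5 lay above its simulated value, which was also below 20.1. In all 3 knockdown libraries 276 regions were called lower and 8 higher. The correlation of log2 ratios across regions was 0.437 for shSpt4 and shSpt5, 0.411 for shSpt4 and shNelfE and 0.357 for shSpt5 and shNelfE, with 0.472, 0.465 and 0.488 in simulations of unchanged libraries. The covariances were 0.313, 0.209 and 0.220, each beside a simulated 0.177 or 0.178. Regions are not independent replicates, and part of the excess in shared calls may come from the shared control, which is 1 library and cannot be split.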

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

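All tests for explanations in this part were chosen after the data had been seen, and all but the test with held-out summits and the fit on region strength, width and shape after the value they measure had been seen. The share of reads on the mitochondrial genome and the share of lines in the second read category were above the control in every knockdown library. Flow cell and passage number differ between the control and the knockdown libraries too, and cannot be told apart from knockdown here. The mitochondrial genome held 0.0524% of reads in shSpt4, 0.0702% in shSpt5 and 0.0380% in shNelfE, against 0.0283% in shControl. The second read category made up 6.96% of reads in shSpt4, 6.96% in shSpt5 and 6.95% in shNelfE, against 6.72% in shControl.

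The first pattern was the lower and flatter Pol II profile: a uniform loss of enrichment would leave the shape above background unchanged, but at isolated regions above local background the central ratio of shSpt5 to shControl was 0.686 times (0.653 to 0.715) the ratio at 1 to 2 kb. Over all regions with no background taken off, summits from a random part of the knockdown tags gave 0.731 (0.712 to 0.749) in the rest of the tags, beside 0.732 with the pooled summits, which argues against summits placed by the control and says nothing on enrichment. Against shSpt4 of the same flow cell the isolated-region value for shSpt5 was 0.854 (0.822 to 0.889), which argues against the flow cell as the whole cause of its shape, while the corresponding 0.803 (0.770 to 0.833) of shSpt4 to the control cannot be told apart from flow cell and passage number. The lower level also stays open, since windows with no region were higher in shSpt5 (1.54, 1.53 to 1.55), and both weaker enrichment and a loss of Pol II at the regions give that. A weaker hold of Pol II at the region summits with less Spt5 may account for the shape, as a hypothesis found on these libraries. The tests addressed other explanations, and none tested this hypothesis.

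The second pattern was the near complete loss at some regions in shSpt5. At least 8-fold lower levels were seen at 32 regions with 50 or more tags, where a common factor of 0.585 and counting error would give 0.00949. Loss of the DNA itself is argued against by the tags at 1 to 3 kb from these summits, whose ratio was 0.451 (0.378 to 0.555), higher than the 0.0997 (0.0755 to 0.122) at the centres, although below the 0.799 of all regions. In shSpt4 these 32 regions, chosen on shSpt5, had a median ratio of 0.515 and in shNelfE of 0.553. They may be sites where Pol II depends on Spt5, and secondary changes in gene activity over 4 days of knockdown stay open and untested.

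The third pattern was that changes in shSpt4 and shSpt5, the DSIF subunits, covaried more than either did with shNelfE. The intervals here came from a jackknife over the chromosomes of these libraries and hold no variation between libraries. The shared control adds the same covariance to every pair, yet the difference between the DSIF pair and the mean of the others was 0.0972 (0.0837 to 0.111). After fitting region strength, width, shape, region density and regional background it was 0.0852 (0.0727 to 0.0976), and the fit took up 2.78%, 2.93% and 1.45% of the variance in shSpt4, shSpt5 and shNelfE, which argues against a linear or quadratic dependence on these as the whole cause and leaves other forms open. The shNelfE changes also had the smallest spread, so a weaker response or knockdown of NelfE, which was not tested, would lower its covariances too. A shared action of the DSIF subunits may underlie the difference, as a hypothesis.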

How the results depend on the processing

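Among the settings below, regions from the knockdown libraries, isolated regions, windows with no region, profile background and the wider profile centre were chosen after the data had been seen. No paired analysis was possible because each group held 1 library. The gene travelling ratio (promoter from -30 to 300 bp) and its alternative with a wider promoter were not run, because no annotation of the files' build was used. Level medians, focal medians and the profile's central ratio over its ratio at 1 to 2 kb kept their direction under all settings run for them, except in shNelfE to shSpt4. The shSpt4 to shControl ratio at 1 to 2 kb was 0.896 over all regions and 1.03 (0.996 to 1.08) at isolated regions with local background taken off. In shNelfE to shSpt4 the focal difference was -0.03 as reported and 0.000438 with background subtracted, and the profile's central ratio over its ratio at 1 to 2 kb was 0.938 (0.926 to 0.949) over all regions and 1.04 (1.01 to 1.08) at isolated regions with local background taken off. Most values moved beyond their interval: 30 level medians moved and 12 stayed, 22 focal medians moved, 1 turned and 19 stayed, 8 profile values moved and 4 stayed, 12 shares of tags moved, and 1 correlation moved and 2 stayed. Of the counts of higher regions, 16 stayed within 1.5 times of the reported count, 6 were above and 8 below, and of those of lower regions 20 stayed, 5 were above and 5 below. Where values moved, the cause was not tested, except where the setting itself sets it, as for scaling, fold limits and the library that chose the regions. Depth limits what can be seen: the median region held 14 tags in shSpt5 and 25 in shControl, so that ratios of weak regions carry wide intervals.

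Scaled by windows with no region, the level medians against shControl were -0.70 in shSpt4, -1.40 in shSpt5 and -0.74 in shNelfE, with 42, 16 and 25 regions higher and 3258, 8676 and 3077 lower. Scaled by the median ratio, 389, 698 and 261 were higher and 546, 964 and 246 lower, a scaling that centres the regions and so moves both counts toward each other. Scaled by tags outside the regions, the medians were -0.36, -0.91 and -0.48, with 71 regions higher in shSpt5, and the knockdowns among each other gave -0.53 for shSpt5 to shSpt4, -0.12 for shNelfE to shSpt4 and 0.43 for shNelfE to shSpt5. At a ratio of 1.5, 262 regions were higher and 2123 lower in shSpt4, and 2360 were lower in shNelfE.

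Regions called on shControl alone held 14.1%, 10.1%, 12.9% and 17.8% of tags in shSpt4, shSpt5, shNelfE and shControl. The levels there were -0.45, -0.95 and -0.55 and the focal differences -0.41, -0.85 and -0.45 in shSpt4, shSpt5 and shNelfE, with 24, 15 and 3 regions higher. For shSpt5 to shSpt4 the level was -0.48 and the focal difference -0.44, and for shNelfE to shSpt5 the focal difference was 0.38. Regions called on the knockdown libraries gave levels of -0.21, -0.68 and -0.34, with 772 regions lower in shSpt4 and 620 in shNelfE. At a Poisson p of 1e-12 the shares of tags were 16.0%, 11.6%, 14.5% and 19.2%, the focal difference of shSpt5 was -0.71, and shNelfE had a level of -0.42, a focal difference of -0.34 and 48 regions higher. The level of shNelfE was then -0.12 against shSpt4 and 0.36 against shSpt5.

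With all tags kept, the shares in regions were 18.0%, 13%, 16.6% and 22.1%. Levels were -0.34 in shSpt4 and -0.81 in shSpt5, focal differences -0.30 and -0.71, and 206 regions were higher in shSpt5 and 157 in shNelfE. The level of shNelfE was -0.0693 against shSpt4 and 0.41 against shSpt5. With every library thinned to the shallowest, shSpt4 had a level of -0.32, and shNelfE had -0.0687 against shSpt4 and 0.36 against shSpt5.

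With background subtracted, levels were -0.81 in shSpt5 and -0.41 in shNelfE and focal differences -0.59 and -0.28. For shSpt5 to shSpt4 they were -0.48 and -0.31, and for shNelfE to shSpt5 they were 0.40 and 0.30. With a centre of 250 bp and flanks from 500 bp to 2 kb, the focal differences were -0.25, -0.57 and -0.27 in shSpt4, shSpt5 and shNelfE, -0.31 for shSpt5 to shSpt4, -0.0110 for shNelfE to shSpt4 and 0.29 for shNelfE to shSpt5. At isolated regions they were -0.36, -0.79 and -0.40 against shControl.

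The profile's central ratio over its ratio at 1 to 2 kb was 0.803, 0.686 and 0.836 in shSpt4, shSpt5 and shNelfE at isolated regions with local background taken off. With the background of windows without regions taken off it was 0.949, 0.785 and 0.889. Counted within 500 bp in place of 150 bp, with no background taken off, it was 0.776 in shSpt5 and 0.881 in shNelfE. Most of the flatter shSpt5 shape stayed with this wider centre, where slightly longer fragments (strand offset of 91 bp against 82 bp in shControl) matter less. The shNelfE value moved the same way at an offset of 79 bp, so the change does not measure fragment length. Over regions with at least 50 tags, the correlation of shSpt4 with shSpt5 changes was 0.490, beside 0.474 in simulations of unchanged libraries against the same control. For shSpt4 with shNelfE it was 0.403 beside 0.467, and for shSpt5 with shNelfE 0.362 beside 0.488.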

Other observations

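The tests of neighbouring regions and of windows by region density in this part were chosen after the data had been seen. Changes in normalised tags ran together at neighbouring regions. Between adjacent regions less than 5 kb apart with at least 100 tags over the 4 libraries, the log2 ratios to the control correlated at 0.519 in shSpt4, 0.537 in shSpt5 and 0.406 in shNelfE (265 pairs, which are not independent replicates). At 20 to 50 kb the correlations were 0.226, 0.151 and 0.0341, and at 200 to 1000 kb they were 0.00532, -0.00520 and 0.0176. Differences between the libraries in these correlations were not tested.

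Between the regions, the ratio to the control was lower in region-rich than in region-poor parts of the genome in each knockdown library. In autosomal windows of 1 Mb with at least 11 regions, normalised tags more than 2 kb outside the regions stood at 0.925 of the control in shSpt4 (0.885 to 0.983 over autosomes), 0.932 in shSpt5 (0.859 to 1.01) and 0.984 in shNelfE (0.943 to 1.02). On X such windows stood at 1.04, 1.04 and 1.07. In the 613 windows without a region they stood at 1.32, 1.54 and 1.27, and every autosome had a ratio above 1, from 1.25 to 1.38 in shSpt4, 1.43 to 1.65 in shSpt5 and 1.20 to 1.35 in shNelfE. The 5 mitochondrial regions had median ratios of 1.69 in shSpt4, 2.43 in shSpt5 and 1.20 in shNelfE, of which the last is below the ratio of windows without regions.

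Of the 32 regions with an at least 8-fold lower level in shSpt5, all with 50 or more tags in the pair of libraries, 1 with many tags was on chromosome 9. Chromosome 9, 64973101 to 64974000, held 248 tags in shControl, 224 in shSpt4 and 148 in shNelfE but 26 in shSpt5. Of the 32 regions, 17 had a ratio above 0.5 in shSpt4 and 20 in shNelfE, and their ratios ranged from 0.139 to 1.08 and from 0.367 to 1.04. The 32 were chosen on the ratio of shSpt5 to shControl, which by itself puts the other libraries above shSpt5. It also favours high counts in the control, which lowers the other ratios to that library. Only 1 region was at least 8-fold lower in shSpt4 and 0 were in shNelfE.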
